A study of Sus scrofa with 32 samples.

How the data were processed

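RNA from the longissimus dorsi, the loin muscle, of 32 pigs aged 6 months was sequenced by the authors, with 1 library per pig and 8 pigs in each of 4 breed groups. Per the labels, the muscle was stored frozen, RNA was extracted with a tissue RNA kit and libraries were made with a kit that does not mark the strand. Reads from overlapping genes on opposite strands can therefore not be told apart. The submitters' processing notes name Bowtie 0.12.2, Cufflinks and the build mm8, which is a mouse build, while the gene identifiers in the files are pig Ensembl identifiers. The pig build and annotation behind the counts are not given in the sources used here, so no chromosome positions are given.

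The authors deposited 1 file per library with 4 columns of values per gene. The deposited read numbers are raw counts of uniquely mapped reads per gene, and in all 32 libraries they add up to the total in the file header. The deposited RPKM values are the read numbers divided by the listed length in kilobases and scaled to that total, and recomputing them from the other columns gave the same values within a relative deviation of 2.2e-14. The deposited coverage column is a percent of the gene length covered by reads, with 12 values over 100 and a maximum of 104.53. The deposited length column, in bases, differed between files for 180 of 17930 genes. A gene with no reads in a library was not listed in its file and was given a count of 0. Depth was 21732670 to 29736735 reads per library, and 14241 to 15664 genes were listed per library.

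Groups and replicate numbers were taken from the labels. The 4 groups were Landrace (L), Dapulian (DPL), Landrace x Dapulian (LDPL) and Duroc x Landrace x Dapulian (DLDPL). Beyond the labels, nothing states that the 32 libraries came from separate animals. If they did not, the p-values measure only the spread between these samples, which may be technical. No pair of libraries of 1 group had counts that agreed within sampling noise: the smallest chi-square per degree of freedom was 33.7. The labels give no sex, batch or date.

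Genes with enough reads were kept with filterByExpr of edgeR 4.0.16 (minimum count 10, minimum total count 15), which left 12821 genes holding 99.97% of the reads. Counts were scaled by TMM, and 1 quasi-likelihood negative binomial model with the 4 groups was fitted over the 32 libraries. The common biological coefficient of variation was 0.285. The 6 pairs of groups were tested, and LDPL was also tested against the midpoint of L and DPL on the log2 scale. P-values were adjusted over genes by the Benjamini-Hochberg method, and a gene was called at an adjusted p under 0.05. Unless another tool is named, every adjusted p of a gene is from this edgeR test. The standard error of a log2 change is its size divided by the square root of its F statistic. Levels are counts scaled to the TMM-adjusted library size (CPM), given as mean ± SD over 8 libraries. The plan fixed before the data were examined named limma on log2(RPKM + 1) as the test unless raw counts were present. The files held counts, so edgeR took its place and limma became an alternative.

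Gene symbols came from a reference table of names. A symbol was found for 10836 identifiers, which is 60.4% of those listed, and identifiers without a symbol held 14.5% of the reads. MYOG, IGF2, MYH7, MYH4, FABP4, ADIPOQ and LEP had no symbol among the tested genes and are not analysed here.

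Named genes followed a rule set before the data were examined. For DPL against L it took the 10 largest rises and the 10 largest falls among called genes with a symbol and a mean RPKM of at least 5 in the higher group. For the other pairs it took 6 of each, and for the midpoint 5 of each. It also took up to 4 members with the smallest adjusted p from each of 29 gene lists, and a panel of muscle and fat genes. A few genes that the rule names are not reported here. The lists, also fixed beforehand, cover muscle growth, fibre types, fat, energy metabolism, stress, immunity, proteolysis, the clock, the cell cycle, ribosomes and markers of the cell types that muscle holds besides fibres.

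Each list with at least 3 tested members was compared with all other genes by camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, adjusted over the 29 lists of each comparison. Camera with an estimated correlation and fry were run beside it. Of 203 list tests, 63 were called with the preset correlation, 0 with an estimated correlation and 55 by fry, and 43 were called by both camera and fry. The smallest adjusted p with an estimated correlation was 0.106. The list calls therefore rest on the preset correlation. In 22 list tests the median change, the mean change and the direction of camera differed in sign, and 0 of these were called.

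The score of a list in a library is the mean of its members' log2 CPM after centring each gene over the 32 libraries. Scores and shares of reads were compared between groups by two-sided exact permutation tests, adjusted within their family. Positions of LDPL between L and DPL have 95% intervals from 10000 bootstrap draws. Library similarity was examined by principal components of the 500 most variable genes.

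The tests were tried on simulated negative binomial counts with the depths, mean levels and dispersions of these libraries and changes planted in 1 group. Per fold size, 64 to 67 of the tested genes were changed, and genes were drawn independently. Many more genes were called in the real comparisons with L, so the rates below need not hold there. Over the 7 comparisons, edgeR recovered 25.8% to 46.3% of genes changed 1.5-fold, 69.2% to 82.1% of those changed 2-fold and 92.4% to 98.5% of those changed 4-fold. Its false calls went from 4 among 143 (DLDPL against LDPL) to 11 among 142 (DLDPL against L). Other tools were tried on DPL against L only. There DESeq2 made 20 false calls among 173, limma on log2 CPM 10 among 153 and edgeR 10 among 155.

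The counts of called genes were repeated in 17 other settings, not all of which apply to every comparison. They include limma with pseudocounts of 1 and 0.1, quantile normalisation, array weights, DESeq2 1.42.0, size factors of DESeq2 in edgeR, no filter on low counts, the compared groups alone, and a block on replicate numbers shared by L and LDPL. Further fits, without DPL replicate 19 and without DLDPL replicates 27 and 29 together, were run for single genes and 1 list, and list tests were repeated without single libraries. Coverage of long genes was also used as a covariate in linear models of the oxidative score and the mitochondrial share over the 32 libraries. Leaving out libraries or the mitochondrially encoded genes, and that covariate, were chosen after seeing the data. Other splits of the libraries were also fitted, 50 per comparison with the real one included. A sex covariate was not run, since none of the listed Y-linked symbols was among the tested genes. R was 4.3.3 and Python 3.11.15, with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.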

Results

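Muscle transcriptomes were compared between 4 breed groups of pigs kept in a similar environment on similar feed, with 8 pigs per group. Landrace (L) is a lean commercial breed, Dapulian (DPL) is an indigenous Chinese breed, LDPL is their cross and DLDPL is the cross of Duroc with Landrace x Dapulian. The stated purpose of the series is transcriptional variation between breeds, with myogenesis and adipogenesis as its theme. Mean depth was 26590633 ± 1158018 reads per library in L, 26184718 ± 3068135 in DPL, 24612294 ± 771859 in LDPL and 24972962 ± 2268551 in DLDPL (SD, n = 8). The L libraries have replicate numbers in a series of their own, whereas the other 3 groups share 1 series. No batch is given, so separate handling of the L pigs or libraries and the Landrace breed cannot be told apart in any comparison with L.

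The L libraries stood apart from the other 24. Mean scores on the first principal component, with 27.9% of the variance, were -28 ± 3.4 in L, 17.3 ± 3.5 in DPL, 7.7 ± 6.2 in LDPL and 3 ± 6.5 in DLDPL (SD, n = 8). The gap between L and the nearest other library was 20.1% of the whole range. Mitochondrially encoded genes took 31.3 ± 5.6% of the reads in DPL, 20.8 ± 2.6% in L, 22.9 ± 4.4% in LDPL and 22.7 ± 4.9% in DLDPL (SD, n = 8). By two-sided exact permutation tests in a family of 6, this share was higher in DPL than in L (p = 0.00109, adjusted 0.00654), than in LDPL (p = 0.00668, adjusted 0.0146) and than in DLDPL (p = 0.0073, adjusted 0.0146). Median coverage of long genes, the percent of their length covered by reads, was 90.9 ± 2.3% in DPL, 92.5 ± 0.8% in L, 92 ± 1% in LDPL and 92.2 ± 1.1% in DLDPL. Within groups the mitochondrial share was higher where coverage was lower (r = -0.58). A higher share leaves fewer reads for other genes and may itself lower coverage. Neither this correlation nor coverage as a covariate therefore tests RNA quality. With coverage as a covariate, chosen after the values were seen, the difference of the share from DPL in percentage points was -7.54 ± 2.03 in L, -6.44 ± 1.94 in LDPL and -6.24 ± 1.97 in DLDPL (SE, adjusted p = 0.00278, 0.00518 and 0.0057 in a family of 6).

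**Figure D1:**
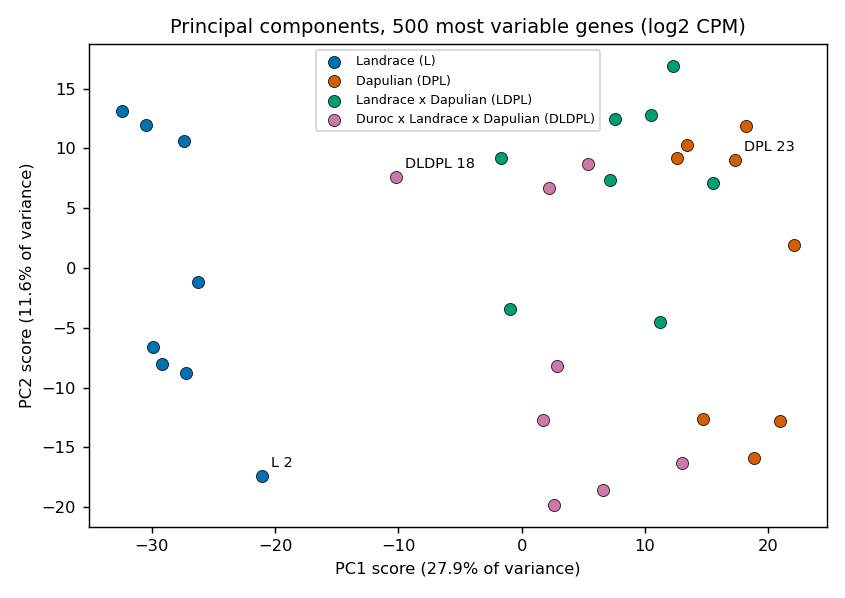
Scores of the 32 libraries on the first and second principal components of log2 CPM over the 500 most variable genes, 1 point per library. The 8 L libraries lie between -32.4 and -21.1 on the first component and the 8 DPL libraries between 12.6 and 22.1.

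The comparison of DPL with L asks how the muscle of the indigenous breed differs from that of the commercial breed. Higher in DPL than in L were 13 of 14 immediate early genes, which respond within minutes to stress or stimulation, all 14 heat shock genes and 23 of 26 nuclear genes of oxidative phosphorylation. Lower were 7 of 10 fast fibre genes, 12 of 21 matrix genes, 7 of 11 cell cycle genes and 5 of 6 genes of immature fibres. NR4A3 (ENSSSCG00000005385), a nuclear receptor induced by stimulation, was at 156 ± 109 CPM in DPL and 0.965 ± 0.417 in L, a log2 change of 7.32 ± 0.62 (SE, n = 8, adjusted p = 1.54e-10). MSTN (ENSSSCG00000016047), which encodes myostatin, an inhibitor of muscle growth, was at 9.66 ± 3.41 CPM in DPL and 38.7 ± 7.15 in L, 4.01-fold lower (log2 change -2 ± 0.3, adjusted p = 4.41e-06). In all, 4873 of 12821 genes were called, 2455 higher and 2418 lower in DPL, of which 1433 differed at least 2-fold.

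Of 14 measured immediate early genes, 13 rose, and 13 adjusted over the list alone. Their median log2 change was 3.08 (camera adjusted p = 1.59e-12, and adjusted p = 0.106 with an estimated correlation). ATF3, a stress-induced transcription factor, rose from 8.44 ± 3.4 to 456 ± 266 CPM (log2 change 5.75 ± 0.52, adjusted p = 5.09e-10). FOS rose from 46.9 ± 32.4 to 886 ± 305 CPM (log2 change 4.24 ± 0.53, adjusted p = 2.08e-07), and MYC rose 10.3-fold. CSRNP1, MAFF, NFIL3 and RCAN1, also among the largest rises, were 23.6-fold, 20.5-fold, 19.6-fold and 19.3-fold higher. RETREG1, a receptor for autophagy of the endoplasmic reticulum, rose from 35 ± 8.47 to 550 ± 226 CPM (log2 change 3.97 ± 0.25, adjusted p = 1.25e-13). All 14 heat shock and chaperone genes rose, and 14 adjusted over the list alone, with a median of 1.5 (camera adjusted p = 9.65e-12, and adjusted p = 0.106 with an estimated correlation). HSPH1 was 7.06-fold, BAG3 4.38-fold, HSP90AA1 3.75-fold and HSPB8 3.57-fold higher.

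Of 26 nuclear genes of oxidative phosphorylation, 23 rose and 0 fell (24 and 0 adjusted over the list alone), with a median of 0.63 (camera adjusted p = 6.39e-12, and adjusted p = 0.223 with an estimated correlation). COX5B, a subunit of cytochrome oxidase, rose from 213 ± 42.4 to 475 ± 102 CPM (log2 change 1.15 ± 0.13, adjusted p = 6.6e-08), and NDUFB9 was 2.14-fold and UQCRC1 1.83-fold higher. Of 23 genes of fatty acid oxidation, 17 rose and 0 fell (17 and 1 adjusted over the list alone), with a median of 0.47 (camera adjusted p = 1.94e-05, and adjusted p = 0.132 with an estimated correlation). PDK4, which restrains the use of glucose, rose from 572 ± 343 to 3690 ± 1610 CPM (log2 change 2.69 ± 0.33, adjusted p = 1.69e-07), and ETFDH and HADHB rose 2.02-fold and 2.12-fold. PPARGC1A, a coactivator of mitochondrial gene expression, was 5.39-fold higher (log2 change 2.43 ± 0.55, adjusted p = 0.000688). Of 18 genes of the TCA cycle, 13 rose and 0 fell (13 and 0 adjusted over the list alone), with a median of 0.35 (camera adjusted p = 0.000154, and adjusted p = 0.354 with an estimated correlation). Of the 13 mitochondrially encoded genes, 10 rose and 0 fell (10 and 0 adjusted over the list alone), with a median of 0.7 (camera adjusted p = 0.00135, and adjusted p = 0.508 with an estimated correlation), among them ND4 by 2.11-fold and COX1 by 1.8-fold. Their share of the reads was 31.3% in DPL and 20.8% in L.

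The slow and fast fibre lists were called in opposite directions. Of 7 slow fibre genes, 4 rose and 0 fell (4 and 0 adjusted over the list alone), with a median of 0.83 (camera adjusted p = 0.0131, and adjusted p = 0.38 with an estimated correlation). CSRP3, a protein of the sarcomere's Z-disc, rose from 80.6 ± 54.1 to 828 ± 364 CPM (log2 change 3.36 ± 0.38, adjusted p = 4.34e-08), and MYH7B rose 2.7-fold. TNNC1 and MYL3 rose 1.77-fold and 1.78-fold. Their calls were lost in 5 and 5 of 11 other settings (adjusted p up to 0.139 and 0.11). Only 7 of the 19 listed slow fibre genes were tested, and MYH7 was not among them. Of 10 fast fibre genes, 1 rose and 7 fell (1 and 8 adjusted over the list alone), with a median of -0.65 (camera adjusted p = 0.0113, and adjusted p = 0.462 with an estimated correlation). PVALB, the calcium buffer parvalbumin, fell from 38 ± 27.9 to 5.74 ± 4.56 CPM (log2 change -2.72 ± 0.53, adjusted p = 0.000151). ATP2A1, the calcium pump of fast fibres, and MYBPC2 were 1.65-fold and 1.67-fold lower. In glycolysis and glycogen metabolism, 5 of 23 genes rose and 12 fell (5 and 13 adjusted over the list alone), and the list was not called (camera adjusted p = 0.138, but 0.00918 downward without L replicate 2). GPI was 1.87-fold lower, whereas UGP2 and GBE1, which build glycogen, were 2.66-fold and 3.78-fold higher.

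Of 21 fibroblast and extracellular matrix genes, 1 rose and 12 fell (1 and 14 adjusted over the list alone), with a median of -0.68 (camera adjusted p = 0.000792, and adjusted p = 0.508 with an estimated correlation). COL3A1 fell from 1030 ± 225 to 231 ± 114 CPM (log2 change -2.16 ± 0.3, adjusted p = 8.16e-07) and COL1A2 was 2.81-fold lower. Of 11 cell cycle genes, 0 rose and 7 fell (0 and 7 adjusted over the list alone), with a median of -1.6 (camera adjusted p = 0.000228, and adjusted p = 0.132 with an estimated correlation). TOP2A and CENPF fell 4.29-fold and 8.08-fold, from 4.56 and 1.83 CPM in L. Of 6 genes of regenerating or immature fibres, 0 rose and 5 fell (0 and 5 adjusted over the list alone), with a median of -1.4 (camera adjusted p = 0.0263, 0.0603 without L replicate 2, and adjusted p = 0.28 with an estimated correlation). MYMK, needed for the fusion of myoblasts, was 2.76-fold lower. The embryonic myosin MYH3 (log2 change -2.65) and the troponin TNNT2 (-3.18) rested in part on L replicate 2, without which the changes were -1.44 and -1.13. MYH3 was at 41.4, 226 and 60.6 CPM in L replicates 1, 2 and 7 and between 3.48 and 12 in the other 5, so its fall rested on 3 L libraries. The reads of MYH8, at 38200 CPM in L, are uncertain, since myosin heavy chain genes are near-identical.

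Myogenic regulators were not called as a list: 4 of 17 rose and 8 fell (5 and 9 adjusted over the list alone, camera adjusted p = 0.224). Besides MSTN, MYOD1, a master regulator of muscle identity, fell (log2 change -0.99 ± 0.29, adjusted p = 0.00643) and IGFBP5 was 3.42-fold lower, whereas MYF6 was 2.42-fold and the stretch-responsive ANKRD2 13.4-fold higher. Of 15 candidate genes for carcass and meat quality in pigs, 1 rose and 7 fell (1 and 7 adjusted over the list alone), with a median of -0.24 (camera adjusted p = 0.0443, 0.06 without L replicate 2, 0.0634 without DPL replicate 23, and adjusted p = 0.132 with an estimated correlation). KIT, a receptor with a role in coat colour, fell from 7.47 ± 2.44 to 0.647 ± 0.364 CPM (log2 change -3.49 ± 0.33, adjusted p = 1.46e-09), and PRKAG3, a regulatory subunit of AMP kinase, was 1.99-fold lower. The other large falls were ADAMTS8 (15.7-fold), PIK3IP1 (5.44-fold), KLHL33 (5.33-fold), KY (5.19-fold), SPOCK2 (4.84-fold) and MAP2K6 (4.77-fold). RPS21 was 6.38-fold lower (log2 change -2.67), but DPL replicate 19 was at 3.01 log2 CPM and the other 7 between -3.68 and -1.75, and without that library the change was -6.77. Ribosomal protein genes have near-identical copies, so the reads of RPS21 are uncertain.

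None of the 4 lists of fat genes was called. Of 9 adipocyte markers, 2 rose and 1 fell (2 and 1 adjusted over the list alone, camera adjusted p = 0.471). LIPE, a lipase of fat mobilisation, rose 2.35-fold and GPD1 fell 1.55-fold. PPARG, the main regulator of adipogenesis, had a log2 change of 0.6 ± 0.34 (adjusted p = 0.167), SCD of 0.75 ± 0.64 (adjusted p = 0.372) and FASN of 0.15 ± 0.54 (adjusted p = 0.855). Of 14 adipogenic regulators, 2 rose, KLF4 by 5.97-fold and GATA2 by 2.43-fold, and 3 fell, among them BMP4 by 2.25-fold (2 and 3 adjusted over the list alone, camera adjusted p = 0.704). In lipogenesis 1 of 15 genes rose, ACSL1 by 2.16-fold, and 2 fell (1 and 1 adjusted over the list alone, camera adjusted p = 0.383). In lipolysis and lipid droplets 3 of 9 rose and 2 fell (4 and 2 adjusted over the list alone, camera adjusted p = 0.678).

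In proteolysis 8 of 17 rose and 1 fell (8 and 1 adjusted over the list alone), with a median of 0.34 (camera adjusted p = 0.00938, and adjusted p = 0.28 with an estimated correlation). FOXO1 and the ubiquitin ligase TRIM63 rose 2.73-fold and 2.35-fold. Of 18 interferon-stimulated genes, 6 rose and 0 fell (6 and 0 adjusted over the list alone), with a median of 0.95 (camera adjusted p = 0.018, and adjusted p = 0.708 with an estimated correlation). Among 14 clock genes, 6 rose and 3 fell (7 and 4 adjusted over the list alone, camera adjusted p = 0.183), with PER1 2.43-fold higher and DBP 3.9-fold lower. The remaining 8 lists were not called: markers of endothelium, smooth muscle, macrophages, lymphocytes, blood, and nerve, and genes of antigen presentation and ribosomes, with camera adjusted p from 0.119 to 0.969. Macrophage markers were called without L replicate 2 (median 0.69, camera adjusted p = 0.016). By limma on log2(RPKM + 1), 1195 genes were higher and 2669 lower, with a median log2 change of all genes of -0.116. After quantile normalisation, which gives all libraries the same distribution, there were 1901 and 2214, with a median of -0.018. With array weights, which leave the scaling as it was and weight the libraries, there were 1816 and 2330, with a median of -0.038. The imbalance thus depended on the scaling and on the weight of single libraries, and these were not told apart.

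**Figure D2:**
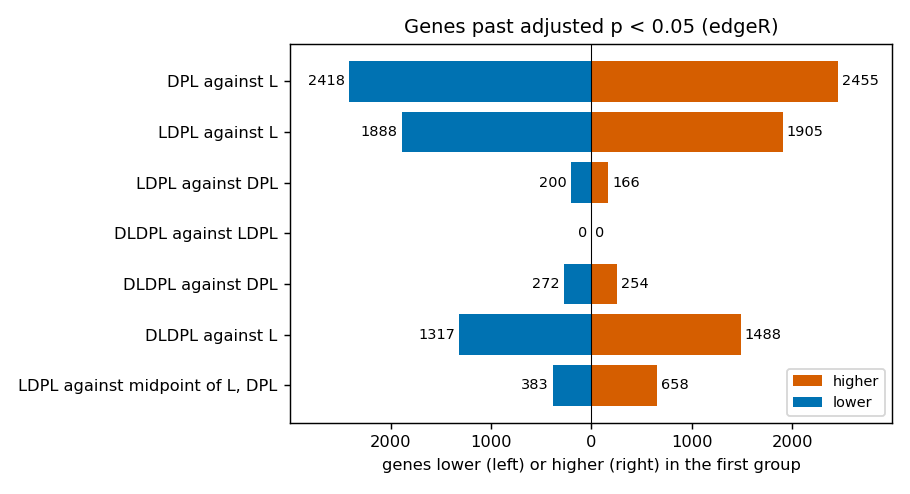
Number of genes called at an adjusted p under 0.05 by edgeR in each comparison, with genes higher in the first-named group drawn to the right and lower ones to the left. DPL against L has 2455 and 2418, and DLDPL against LDPL has 0 in both directions.

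The cross was compared with each parental breed. Against L, 12 of 14 immediate early and 12 of 14 heat shock genes were higher in LDPL, as were NR4A3, RETREG1 and PPARGC1A, and MSTN and COL3A1 were lower. NR4A3 was at 129 ± 81 CPM in LDPL and RETREG1 at 608 ± 237, log2 changes of 7.05 ± 0.62 and 4.12 ± 0.25 (SE, n = 8, adjusted p = 6.53e-10 and 5.24e-14). MSTN was 2.28-fold lower (adjusted p = 0.00259) and PPARGC1A 5.34-fold higher (adjusted p = 0.0011). In all, 3793 genes were called, 1905 higher and 1888 lower.

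Of 14 immediate early genes, 12 rose in LDPL against L and 0 fell (14 and 0 adjusted over the list alone), with a median of 2.28 (camera adjusted p = 6.52e-12, and adjusted p = 0.168 with an estimated correlation). ATF3, MAFF and CSRNP1 were 26.3-fold, 19.3-fold and 17.2-fold higher. Of 14 heat shock genes 12 rose (13 adjusted over the list alone), with a median of 1.1 (camera adjusted p = 5.08e-09, and adjusted p = 0.168 with an estimated correlation), such as HSPH1 by 2.22 and BAG3 by 1.81 on the log2 scale. In oxidative phosphorylation 12 of 26 rose (14 adjusted over the list alone), with a median of 0.31 (camera adjusted p = 0.000575, and adjusted p = 0.678 with an estimated correlation). In proteolysis 8 of 17 rose and 1 fell (8 and 1 adjusted over the list alone; camera adjusted p = 0.00844, and adjusted p = 0.435 with an estimated correlation), with FOXO1 up by 1.77 on the log2 scale. In the slow fibre list 3 of 7 rose (3 adjusted over the list alone; camera adjusted p = 0.0198, 0.0824 without L replicate 2, and adjusted p = 0.46 with an estimated correlation), CSRP3 by 2.7 and MYH7B by 1.14. In the matrix list 8 of 21 fell (8 adjusted over the list alone; camera adjusted p = 0.0163, 0.075 without L replicate 2, and adjusted p = 0.765 with an estimated correlation), COL3A1 by a log2 change of -1 ± 0.29. In the cell cycle list 3 of 11 fell (5 adjusted over the list alone; camera adjusted p = 0.0163, and adjusted p = 0.435 with an estimated correlation), AURKB by -1.03 on the log2 scale.

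Among the largest falls in LDPL against L, KLHL33, MAP2K6 and KY were 5.19-fold, 4.43-fold and 4.43-fold lower. TNNT2 (log2 change -3.31) and MYH3 (-2.92) rested in part on L replicate 2, without which they were -1.26 and -1.7, and MYH3 was high in L replicates 1 and 7 besides. PON3 changed by -1.97 ± 0.69 (adjusted p = 0.0298), and by -1.75 without L replicate 2, where its adjusted p was 0.0593. Its call was lost in 8 of 12 other settings, with changes of -2.18 to -0.47 and adjusted p of up to 0.649. The calls of AURKB, TNNT2 and MYH7B were lost in 2 of 8, 2 of 12 and 1 of 12 (adjusted p up to 0.197, 0.112 and 0.07). Macrophage markers were called higher in LDPL than in L without L replicate 2 (median 0.81, camera adjusted p = 0.0442).

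Against DPL, NDUFV1, UQCRC1, HADHB and IRF9 were lower in LDPL, and PVALB, LDHA and COL3A1 were higher. NDUFV1, a subunit of complex I, was at 77.2 ± 8.47 CPM in LDPL and 113 ± 20.2 in DPL, and PVALB at 32.8 ± 35.5 and 5.74 ± 4.56. Their log2 changes were -0.55 ± 0.1 and 2.51 ± 0.53 (SE, n = 8, adjusted p = 0.0026 and 0.00849). In all, 366 genes were called, 166 higher and 200 lower. Without DPL replicate 23 there were 264.

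Of 26 nuclear genes of oxidative phosphorylation, 10 fell in LDPL against DPL and 0 rose (19 and 0 adjusted over the list alone), with a median of -0.37 (camera adjusted p = 2.36e-13, and adjusted p = 0.209 with an estimated correlation). UQCRC1 changed by -0.55 ± 0.11 (adjusted p = 0.00695). In the TCA cycle 4 of 18 fell, such as PDHA1 by -0.59 (10 adjusted over the list alone; camera adjusted p = 1.39e-08, and adjusted p = 0.209 with an estimated correlation). In fatty acid oxidation 5 of 23 fell, HADHB by -0.63 (13 adjusted over the list alone; camera adjusted p = 5.1e-07, and adjusted p = 0.209 with an estimated correlation). Of the 13 mitochondrially encoded genes 0 passed the test over all genes and 11 fell adjusted over the list alone, with a median of -0.53 (camera adjusted p = 1.29e-07, and adjusted p = 0.269 with an estimated correlation). Their share of the reads was 22.9% in LDPL and 31.3% in DPL. In lipolysis and lipid droplets 2 of 9 fell, PNPLA2 by -0.7 and PLIN5 by -1.38 (2 adjusted over the list alone; camera adjusted p = 0.0183, and adjusted p = 0.209 with an estimated correlation). PLIN5 had an adjusted p of 0.107 without DPL replicate 23. None of 9 adipocyte markers passed the test (0 adjusted over the list alone), with a median of -0.72 (camera adjusted p = 0.022, and adjusted p = 0.445 with an estimated correlation).

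Of 18 interferon-stimulated genes, 2 fell in LDPL against DPL, IRF9 by -0.91 and IFI44L by -1.13 (4 adjusted over the list alone), with a median of -1.11 (camera adjusted p = 1.02e-08, and adjusted p = 0.269 with an estimated correlation). In the heat shock list 1 of 14 fell, HSP90AB1 by -0.55 (4 adjusted over the list alone; camera adjusted p = 5.73e-05, and adjusted p = 0.269 with an estimated correlation). In the immediate early list 0 of 14 passed and 4 fell adjusted over the list alone (median -0.41, camera adjusted p = 0.00874, and adjusted p = 0.495 with an estimated correlation). The calls of HSP90AB1, IFI44L and IRF9 were lost in 5, 4 and 3 of 10 other settings (adjusted p up to 0.21, 0.0888 and 0.0824), with lower values in LDPL in all of them.

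Of 10 fast fibre genes 3 rose in LDPL against DPL, PVALB, MYL1 by 0.6 and TPM1 by 0.58 (3 adjusted over the list alone; camera adjusted p = 0.00343, and adjusted p = 0.395 with an estimated correlation). In glycolysis 3 of 23 rose, LDHA by 0.71, GPI by 0.49 and TPI1 by 0.53 (3 rose and 1 fell adjusted over the list alone; camera adjusted p = 0.0103, and adjusted p = 0.495 with an estimated correlation). In the cell cycle list 2 of 11 rose, TOP2A by 1.39 and CENPF by 2.14, and TPX2 fell by 0.85 (4 rose and 1 fell adjusted over the list alone; camera adjusted p = 0.00206, and adjusted p = 0.209 with an estimated correlation). In the matrix list 1 of 21 rose, COL3A1 by 1.17 ± 0.29 (3 adjusted over the list alone; camera adjusted p = 0.0256, and adjusted p = 0.592 with an estimated correlation). None of 26 ribosomal protein genes passed (0 adjusted over the list alone), with a median of 0.11 (camera adjusted p = 0.00874, and adjusted p = 0.568 with an estimated correlation). MYF5, a regulator of muscle precursor cells, changed by -1.75 ± 0.39 (adjusted p = 0.0121). Outside the lists, ENHO, CAPN6, ITGB1BP2 and TGFB2 were 2.31-fold, 2.26-fold, 2.07-fold and 1.96-fold higher, and UBE2L6, UCHL1, ERAP1 and AP5B1 were 2.49-fold, 2.39-fold, 2.29-fold and 2.24-fold lower. UCHL1 and TPM1 had adjusted p of 0.0539 and 0.0541 without DPL replicate 23. Over 10 other settings the calls of UCHL1, PLIN5, TPX2, UBE2L6, TPM1, COL3A1 and PNPLA2 were lost in 7, 6, 4, 2, 2, 1 and 1 (adjusted p up to 0.188, 0.107, 0.142, 0.0649, 0.0652, 0.0741 and 0.0741), and that of CENPF in 1 of 6 (0.0502). On log2(RPKM + 1) limma called 157 genes higher and 52 lower, with a median of all genes of 0.08, with array weights 246 and 103, with a median of 0.048, and after quantile normalisation 142 and 145, with a median of 0.008. NDUFA9, SDHA and PDHA1 were not called in some settings but stayed lower in all that were run, with log2 changes of -0.47 to -0.35, -0.44 to -0.31 and -0.6 to -0.48.

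Whether LDPL departs from the mean of its parental breeds was asked by testing it against their midpoint on the log2 scale, so a gene off the midpoint can still lie between the breeds, as NR4A3 did (0.965 CPM in L, 129 in LDPL and 156 in DPL). Where the breeds differ, that midpoint lies below their mean in CPM, so a gene above the midpoint need not exceed that mean. The midpoint includes L, so a difference in handling between L and the other groups would enter it. LDPL was above the midpoint in 7 of 14 immediate early genes, 3 of 14 heat shock genes and 5 of 14 clock genes. NR4A3 lay 3.39 ± 0.4 above the midpoint (SE, adjusted p = 1.88e-06), RETREG1 2.13 ± 0.18 (adjusted p = 1.43e-09) and the thiamine transporter SLC19A2 2.05 ± 0.2 (adjusted p = 1.54e-08). In all, 1041 genes were called, 658 above and 383 below. After quantile normalisation 585 were above and 517 below.

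Of 14 immediate early genes, 7 lay above the midpoint and 0 below (8 and 0 adjusted over the list alone), with a median of 0.83 (camera adjusted p = 1.67e-06, and adjusted p = 0.744 with an estimated correlation). In the heat shock list 3 of 14 were above, such as BAG3 by 0.74 and HSPH1 by 0.81 (4 adjusted over the list alone; camera adjusted p = 0.0032, and adjusted p = 0.746 with an estimated correlation). Of 14 clock genes 5 were above, among them RORA by 0.88, CRY2 by 0.72 and PER1 by 0.55 (6 above and 1 below adjusted over the list alone; camera adjusted p = 0.0339, and adjusted p = 0.744 with an estimated correlation). Of 18 interferon-stimulated genes 1 was below, IRF9 by -0.76 (3 adjusted over the list alone; camera adjusted p = 0.00136, and adjusted p = 0.784 with an estimated correlation). MAFF was 4.27-fold above, and CITED2, ERAP1, KLHL33, FBXL4 and UBE2L6 were 2.35-fold, 2.31-fold, 2.25-fold, 2.18-fold and 2.07-fold below. The call of HSPH1 was lost in 1 of 11 other settings (adjusted p = 0.0509). Without L replicate 2, genes of the TCA cycle and mitochondrially encoded genes were called below the midpoint (medians -0.16 and -0.25, camera adjusted p = 0.0122 and 0.0153), and proteolysis and ribosomal genes above it (0.2 and 0.16, camera adjusted p = 0.0438 and 0.0251). Ribosomal genes were also called without DPL replicate 23 (0.17, camera adjusted p = 0.00995).

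**Figure D3:**
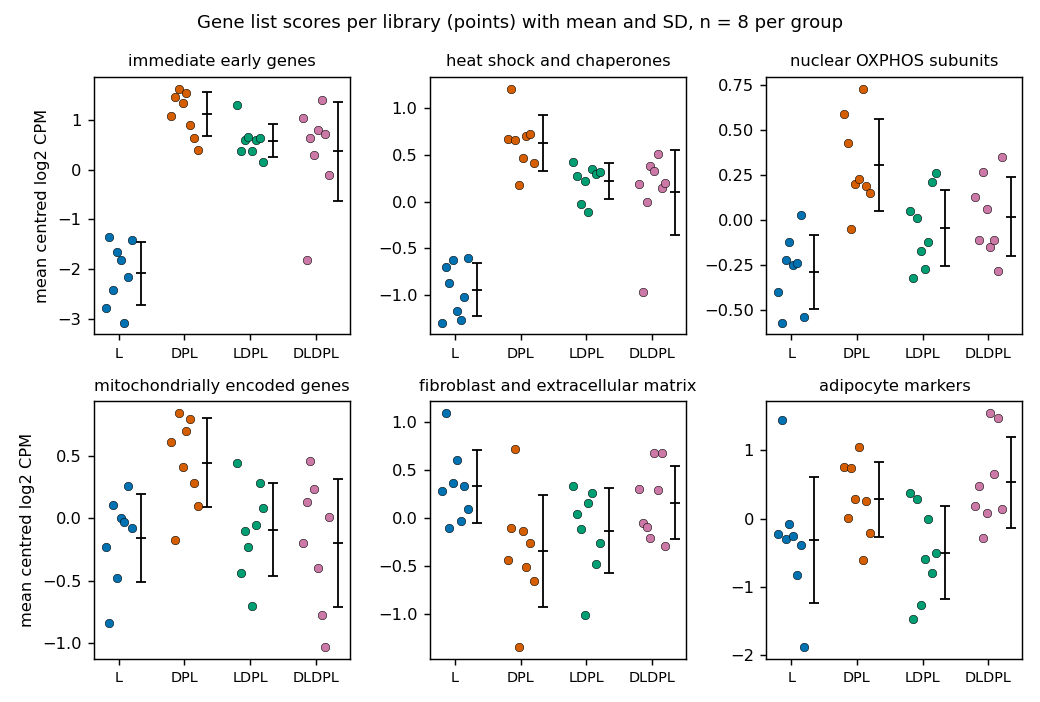
Scores of 6 gene lists, as mean centred log2 CPM, in each library (points), with the mean and SD of each group of 8. For immediate early genes, 1 library outside L, DLDPL replicate 18 at -1.82, lies within the range of the L libraries.

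The comparison of DLDPL with LDPL sets the cross with Duroc against the cross without it. The shares of Landrace and Dapulian differ too, so a difference could not be credited to Duroc alone. No gene was called by edgeR. CIDEC, a lipid droplet protein, was at 7.44 ± 6.57 CPM in DLDPL and 1.8 ± 1.15 in LDPL (SD, n = 8, log2 change 2.06 ± 0.53, adjusted p = 0.17), and PPARG at 7.02 ± 5.82 and 2.86 ± 1.16 (log2 change 1.3 ± 0.34, adjusted p = 0.175). At an unadjusted p under 0.05 there were 969 genes, 7.6% of those tested, and the smallest adjusted p was 0.0927. DESeq2 called 33 genes, 26 higher and 7 lower, and limma on log2(RPKM + 1) called 0. In the simulation of DPL against L, DESeq2 made more false calls than edgeR. Whether these 33 are false calls was not tested. CIDEC was at 17.2 and 18.7 CPM in DLDPL replicates 27 and 29 and between 2.41 and 5.14 in the other 6, and without both its log2 change was 1.13 (adjusted p = 0.654). Without DLDPL replicate 27 the change of PPARG was 0.83 (adjusted p = 0.503).

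Of 9 adipocyte markers, 0 passed the test over all genes in DLDPL against LDPL and 5 rose adjusted over the list alone, with a median of 1.22 (camera adjusted p = 9.68e-05, and adjusted p = 0.485 with an estimated correlation). The adipocyte score was 0.53 ± 0.66 in DLDPL, -0.5 ± 0.68 in LDPL and 0.29 ± 0.55 in DPL (SD, n = 8). By exact permutation tests, DLDPL differed from DPL by 0.24 (p = 0.435, adjusted 0.503) and LDPL by -0.79 (p = 0.0256, adjusted 0.0742). The difference between the crosses therefore need not be a rise in DLDPL. Without DLDPL replicates 27 and 29 the list had a median of 0.6 (camera adjusted p = 0.00708). PLIN1, which coats lipid droplets, had a log2 change of 1.97 ± 0.64 (adjusted p = 0.364), and of 0.81 (adjusted p = 0.845) without these libraries, where it was at 43.6 and 43.1 CPM, against 3.19 to 15.1 in the other 6. Of 21 matrix genes 0 passed (0 adjusted over the list alone), with a median of 0.22 (camera adjusted p = 0.00238, 0.0681 without DLDPL replicate 27, 0.0502 without DLDPL replicate 29, and adjusted p = 0.809 with an estimated correlation). SCD and FASN, enzymes of fatty acid synthesis, both had a log2 change of 2.06 (adjusted p = 0.326 and 0.191). Without DLDPL replicate 29 these were 0.3 and 1 (adjusted p = 0.946 and 0.654). Chosen after their values were seen, CIT was called by limma with array weights (log2 change 0.97, adjusted p = 0.0486). With no filter on low counts GSTO2 (-7.68, adjusted p = 0.00028) and ENSSSCG00000021404 (-5.91, adjusted p = 0.0204) were called.

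Against DPL, COL3A1, COL1A2 and PVALB were higher in DLDPL, and 7 of 26 nuclear genes of oxidative phosphorylation and 4 of 14 heat shock genes were lower. Several calls of the lower genes were lost in other settings, as given below. COL3A1 was at 710 ± 282 CPM in DLDPL and 231 ± 114 in DPL, a log2 change of 1.62 ± 0.29 (SE, n = 8, adjusted p = 0.00153), and PVALB was 4.27-fold higher (adjusted p = 0.0194). SCD and FASN were 6.83-fold and 4.38-fold higher (log2 changes 2.77 ± 0.67 and 2.13 ± 0.55, adjusted p = 0.0145 and 0.0232). Both rested on DLDPL replicate 29, without which the changes were 1.02 (adjusted p = 0.213) and 1.08 (adjusted p = 0.174). FASN was also high in DLDPL replicate 27 (73.2 CPM, against 6.99 to 21.5 in the 6 others), and without both libraries its change was 0.28 (adjusted p = 0.753) and that of SCD 0.96 (adjusted p = 0.293). In all, 526 genes were called, 254 higher and 272 lower. Without DLDPL replicate 29 there were 345 and without DLDPL replicate 18 there were 357.

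Of 21 matrix genes, 5 rose in DLDPL against DPL and 0 fell (8 and 0 adjusted over the list alone), with a median of 0.44 (camera adjusted p = 8.88e-06, and adjusted p = 0.399 with an estimated correlation). COL1A2 changed by 1.25 ± 0.26 (adjusted p = 0.00448). In the smooth muscle list 1 of 9 rose, CNN1 by 1.01 (4 adjusted over the list alone; camera adjusted p = 0.0158, and adjusted p = 0.429 with an estimated correlation). In the cell cycle list 2 of 11 rose, CENPF by 2.32 and TOP2A by 1.36 (5 adjusted over the list alone; camera adjusted p = 0.0036, and adjusted p = 0.317 with an estimated correlation). Of 6 immature fibre genes 1 rose, MYMK by 1.38 ± 0.28 (3 adjusted over the list alone; camera adjusted p = 0.0323, and adjusted p = 0.317 with an estimated correlation). Of 10 fast fibre genes 2 rose, PVALB and MYL1 (4 adjusted over the list alone; camera adjusted p = 0.0324, 0.0622 without DLDPL replicate 18, and adjusted p = 0.515 with an estimated correlation). In glycolysis 3 of 23 rose, such as GPI by 0.57 and LDHA by 0.77 (5 adjusted over the list alone; camera adjusted p = 0.01, and adjusted p = 0.458 with an estimated correlation). In the ribosomal list 1 of 26 rose, RPL14 by 0.6 (3 adjusted over the list alone; camera adjusted p = 0.0369, 0.172 without DLDPL replicate 18, and adjusted p = 0.78 with an estimated correlation). MYL1 had an adjusted p of 0.0823 without DLDPL replicate 18, and RPL14 one of 0.0637 to 0.0685 without DLDPL replicate 18, 27 or 29. CAPN6 and PENK were 2.73-fold and 2.67-fold higher, and AP5B1, APOD and LPCAT3 were 2.61-fold, 2.4-fold and 2.33-fold lower.

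Of 26 nuclear genes of oxidative phosphorylation, 7 fell in DLDPL against DPL and 0 rose (14 and 0 adjusted over the list alone), with a median of -0.3 (camera adjusted p = 3.69e-09, and adjusted p = 0.317 with an estimated correlation). Of the mitochondrially encoded genes 1 of 13 fell, ND1 by -0.73 (13 adjusted over the list alone; camera adjusted p = 3.69e-09, and adjusted p = 0.317 with an estimated correlation). In the TCA cycle 2 of 18 fell, PDHA1 by -0.56 and SDHA by -0.37 (1 rose and 11 fell adjusted over the list alone; camera adjusted p = 3.86e-05, and adjusted p = 0.317 with an estimated correlation). In fatty acid oxidation 4 of 23 fell, such as HADHA by -0.62 ± 0.12 (8 adjusted over the list alone; camera adjusted p = 0.000533, and adjusted p = 0.317 with an estimated correlation). In the heat shock list 4 of 14 fell, such as HSP90AB1 by -0.64 (8 adjusted over the list alone; camera adjusted p = 7.63e-07, and adjusted p = 0.317 with an estimated correlation). None of 14 immediate early genes passed (0 adjusted over the list alone), with a median of -0.61 (camera adjusted p = 0.000138, and adjusted p = 0.354 with an estimated correlation). DLDPL replicate 18 scored low in both lists (-0.97 for heat shock and -1.82 for immediate early genes), and without it their medians were -0.44 and -0.44 (camera adjusted p = 3.15e-05 and 0.0102). Of 18 interferon-stimulated genes 1 fell, IRF9 by -0.85 (2 adjusted over the list alone; camera adjusted p = 4.2e-08, and adjusted p = 0.317 with an estimated correlation). On log2(RPKM + 1) limma called 387 genes higher and 52 lower, with a median of all genes of 0.11, with array weights 320 and 93, with a median of 0.05, and after quantile normalisation 225 and 221, with a median of 0.001. CSRP3 (log2 change -1.39), ANKRD2 (-1.38) and UCHL1 (-1.17) fell, but CSRP3 had an adjusted p of 0.0575 without DPL replicate 23 and ANKRD2 of 0.0503 without DLDPL replicate 18. Leaving out DPL replicate 23 or any of DLDPL replicates 18, 27 and 29 also ended the calls of UCHL1 (adjusted p 0.0614 to 0.0938), ND1 (0.0599 to 0.0859) and SDHA (0.074 to 0.0854). IRF9 was not called without DLDPL replicate 18, 27 or 29 (0.0534 to 0.0558), nor PDHA1 without DLDPL replicate 18 or 29 (0.0599 and 0.0578). Over all 13 other settings the calls of SDHA, UCHL1, IRF9, PDHA1, RPL14, MYL1, HSP90AB1, ANKRD2, APOD and CSRP3 were lost in 10, 9, 7, 5, 4, 3, 2, 2, 2 and 1, with adjusted p of up to 0.26, 0.143, 0.0941, 0.0797, 0.0685, 0.0863, 0.117, 0.0759, 0.0601 and 0.0575. Calls of the heat shock genes HSPB8, STIP1 and HSP90AA1 were lost in 8, 7 and 4 (adjusted p up to 0.166, 0.2 and 0.08). Those of COX5B, NDUFB10, NDUFV1 and UQCRC1 were lost in 6, 3, 3 and 3 (up to 0.202, 0.151, 0.0682 and 0.0571). These genes stayed lower in DLDPL in all settings that were run.

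Against L, 13 of 14 immediate early genes, 12 of 14 heat shock genes and 14 of 26 nuclear genes of oxidative phosphorylation were higher in DLDPL, as was PPARG, and MSTN was lower. NR4A3 was at 206 ± 127 CPM in DLDPL (log2 change 7.72 ± 0.63, SE, n = 8, adjusted p = 1.41e-10), and PPARG was 2.5-fold higher (log2 change 1.32 ± 0.34, adjusted p = 0.00506, and 0.86 with an adjusted p of 0.0357 without DLDPL replicate 27). MSTN was 2.36-fold lower (adjusted p = 0.00275) and PPARGC1A 7.23-fold higher (adjusted p = 0.000353). SCD changed by 3.52 ± 0.69 and FASN by 2.28 ± 0.56, and by 1.76 (adjusted p = 0.00607) and 1.21 (adjusted p = 0.0467) without DLDPL replicate 29. Without DLDPL replicates 27 and 29 they changed by 1.7 (adjusted p = 0.0125) and 0.42 (adjusted p = 0.461). In all, 2805 genes were called, 1488 higher and 1317 lower.

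Of 14 immediate early genes, 13 rose in DLDPL against L and 0 fell (13 and 0 adjusted over the list alone), with a median of 2.44 (camera adjusted p = 1.17e-12, and adjusted p = 0.145 with an estimated correlation). In the heat shock list 12 of 14 rose, such as HSPH1 by 2.21 (12 adjusted over the list alone; camera adjusted p = 1.99e-09, and adjusted p = 0.145 with an estimated correlation). In oxidative phosphorylation 14 of 26 rose, such as NDUFB9 by 0.68 (17 adjusted over the list alone; camera adjusted p = 9.9e-07, and adjusted p = 0.494 with an estimated correlation). In fatty acid oxidation 8 of 23 rose and 2 fell, with PPARA up by 1.4 and PDK4 by 1.78 (8 and 2 adjusted over the list alone; camera adjusted p = 0.00255, and adjusted p = 0.357 with an estimated correlation). In proteolysis 7 of 17 rose and 1 fell, with FOXO1 up by 1.66 (7 and 1 adjusted over the list alone; camera adjusted p = 0.00411, and adjusted p = 0.326 with an estimated correlation). In the slow fibre list 2 of 7 rose, CSRP3 by 1.97 and MYH7B by 1.16 (2 adjusted over the list alone; camera adjusted p = 0.0382, 0.141 without L replicate 2, and adjusted p = 0.507 with an estimated correlation). In the cell cycle list 4 of 11 fell, such as AURKB by -1.31 (6 adjusted over the list alone; camera adjusted p = 0.00596, and adjusted p = 0.326 with an estimated correlation). Of 5 lymphocyte markers 4 fell, such as CD8A by -1.79 (4 adjusted over the list alone; camera adjusted p = 0.0435, 0.122 without L replicate 2, and adjusted p = 0.507 with an estimated correlation). Of these, CD2 and CD3D had adjusted p of 0.168 and 0.0839 without L replicate 2. Without that library adipocyte markers and macrophage markers were called higher in DLDPL than in L (medians 1.54 and 0.55, camera adjusted p = 0.049 and 0.0415) and fast fibre genes lower (-0.38, camera adjusted p = 0.0107). Genes of the TCA cycle were called higher without DLDPL replicate 27 or 29 (camera adjusted p = 0.0494 and 0.0311), and clock genes without DLDPL replicate 29 (0.0433). PARM1, PIK3IP1, NFE2L3 and KLHL33 were 3.82-fold, 3.66-fold, 3.65-fold and 3.38-fold lower. MYH3 (log2 change -2.67) and TNNT2 (-2.54) were not called without L replicate 2, with changes of -1.45 (adjusted p = 0.0548) and -0.49 (adjusted p = 0.278), and MYH3 was high in L replicates 1 and 7 besides.

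**Figure D4:**
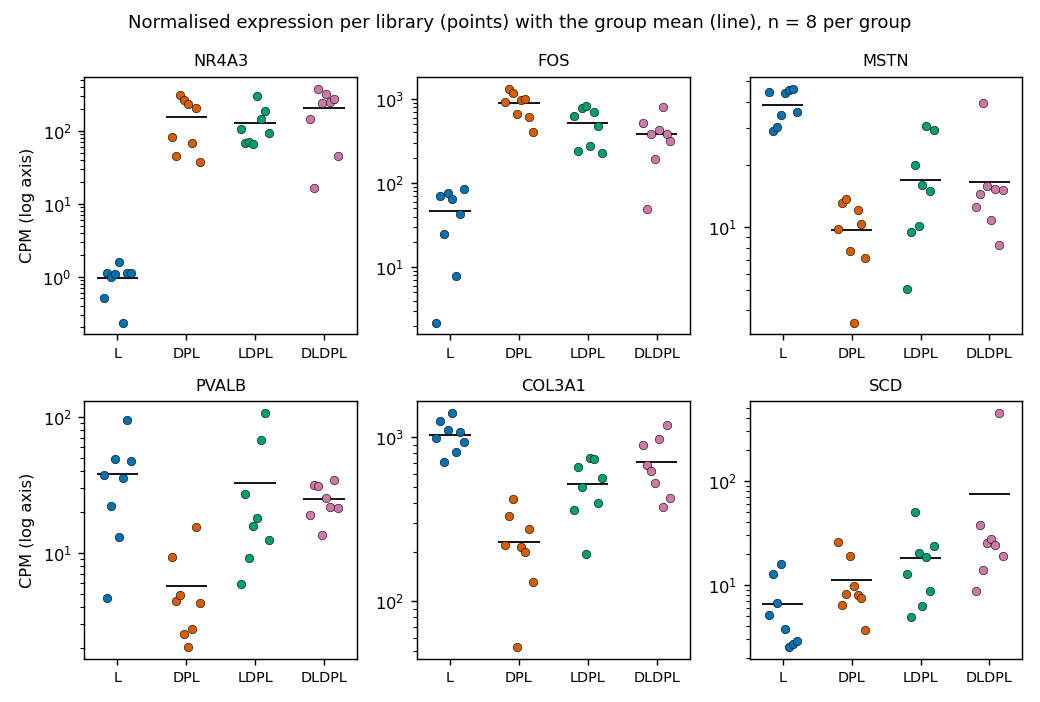
Expression of NR4A3, FOS, MSTN, PVALB, COL3A1 and SCD in CPM on a log axis, 1 point per library, with a line at the mean of each group of 8. NR4A3 has a mean of 0.965 CPM in L and of 129 to 206 CPM in the other groups, and 1 DLDPL library lies far above the rest for SCD.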

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

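All tests of explanations in this part were chosen after the results they concern were seen, and the tests on fast fibre genes, on reads with no TMM and on the adipocyte line replaced earlier ones that were undecided or could not decide after the tables had been seen.

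Immediate early genes scored -2.09 ± 0.64 in L, 1.13 ± 0.45 in DPL, 0.59 ± 0.33 in LDPL and 0.37 ± 1 in DLDPL (SD, n = 8), and heat shock genes followed the same order. The tables argue against a breed effect additive on the log2 scale as the whole cause. On that scale LDPL lay at 0.83 of the way from L to DPL (95% bootstrap interval 0.74 to 0.94) and not at 0.5. An effect additive in CPM would also put LDPL above 0.5 on the log2 scale, so this position cannot decide on it. The tables also argue against L replicate 2 as the source of the difference between DPL and L, since 4778 genes were called without it. Separate handling of the Landrace pigs or libraries stays open and cannot be told apart from the breed: only 1 of the 24 other libraries, DLDPL replicate 18, fell within the range of L, and the numbering series follows the breed. A breed effect that is additive in CPM, or not additive on either scale, may also contribute and was not tested apart from handling.

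Nuclear genes of oxidative phosphorylation scored 0.35 lower in LDPL than in DPL (difference -0.35, two-sided exact permutation p = 0.00948, adjusted 0.0455 over 24 score tests, and 0.0632 over the 20 without those added later). Mitochondrial transcripts taking reads from other genes would lower the other genes in DPL, which is the opposite of this pattern. Per read and with no TMM the difference was still -0.25 (exact p = 0.0292, adjusted 0.0742), so by the unadjusted p alone it did not rest on TMM. In DLDPL against DPL it was -0.15 (exact p = 0.136), so this does not extend to DLDPL. Lower coverage of long genes went with higher scores within groups (r = -0.38). With coverage as a covariate the difference from DPL was -0.29 ± 0.11 in LDPL and -0.21 ± 0.11 in DLDPL (SE). The covariate cannot decide, since a higher mitochondrial share may itself lower coverage, so lower coverage or RNA quality stays open as a cause. By the unadjusted p alone, the tables argue against DPL replicate 23, with the lowest coverage, as the whole source in LDPL. Without that library the difference was -0.29 in LDPL (exact permutation p = 0.0194, adjusted 0.0742) and -0.23 in DLDPL (exact permutation p = 0.0617). Fewer muscle fibres among other cells in LDPL would lower fast fibre genes too, if the mix of fibre types stayed the same. The fast fibre score was higher in LDPL by 0.41 (exact p = 0.00186, adjusted 0.0199), while the test this replaced, on matrix minus endothelial scores, gave 0.25 (exact p = 0.345). Neither test can decide, since a change in the mix of fibre types could raise fast fibre genes whatever the number of fibres. A shift from slow to fast fibres may underlie the difference and stays open, since slow fibre genes scored -0.25 in LDPL against DPL (exact p = 0.211), and another breed effect was not tested.

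SCD and FASN were called higher in DLDPL than in DPL, with SCD at 8.81 log2 CPM in DLDPL replicate 29 and between 3.15 and 5.25 in the other 7 pigs. These calls rested on that pig, since the log2 change of SCD without it was 1.02 and neither gene was then called, and the change of FASN rested on DLDPL replicate 27 too, falling to 0.28 without both. The SCD of DLDPL replicate 29 lay 4.24 above the value that its adipocyte score predicts from the other 31 libraries (predicted 4.56, 95% prediction interval 2.32 to 6.81), and FASN lay 3.25 above. That pig was picked for its high SCD, so the interval is not a fair test. The test this replaced was its adipocyte score of 1.47, close to the 1.54 of DLDPL replicate 27, whose SCD was lower by a ratio of 16.2. The ratio of replicate 29 to replicate 27 was 0.988 for PLIN1, 1.09 for CIDEC and 2.72 for FASN. For FASN, also high in replicate 27, more adipocytes stay open. For SCD these ratios argue against more adipocytes as the whole source in replicate 29. A state of this pig that raises fatty acid synthesis stays open, and no biological explanation was tested.

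The values below stood apart by the gap between 1 library and the nearest other one of its group, relative to the range of the group. Such gaps were found in 40 of 332 groups of values, and chance gives about 1 in 20. Gene values are log2 CPM and list values are scores.

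L replicate 2 had 15664 genes listed and a TMM factor of 1.44, against at most 15040 and 1.1 in the other L libraries. In that library fast fibre genes scored -0.55, glycolysis genes -0.58, macrophage markers 1.89 and blood markers -3.2. Its TNNT2 was at 5.64, CAPN6 at 7.04, IFI44L at 5.37, SPOCK2 at 1.25, MAP2K6 at 2.36 and NFE2L3 at 3.26. Smooth muscle markers scored -0.78 in L replicate 8, SLC19A2 was at 3.79 in L replicate 9 and RETREG1 at 5.77 in L replicate 10.

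In DPL, macrophage markers scored 1.33 in replicate 16, SPOCK2 was at -0.12 in replicate 11, and LPCAT3 at 6.28 and MSTN at 1.84 in replicate 21. RPS21 was at 3.01 and CAPN6 at 2.25 in DPL replicate 19, while the other 7 DPL libraries had RPS21 between -3.68 and -1.75.

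In LDPL replicate 4 fast fibre genes scored -0.42 and immediate early genes 1.3. PLIN5 was at -0.08 in LDPL replicate 5, and RPS21 at 3.53 and PON3 at -1.31 in LDPL replicate 10.

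DLDPL replicate 18 had low scores of fatty acid oxidation (-0.24), immediate early genes (-1.82) and heat shock genes (-0.97). DLDPL replicate 28 had a cell cycle score of -0.63, NFIL3 at 6.49 and ERAP1 at 2.36. DLDPL replicate 29 had LPCAT3 at 2.41 besides SCD, and DLDPL replicate 20 had MSTN at 5.31. In DLDPL replicate 32 endothelial markers scored -0.56 and interferon-stimulated genes 2.29, with IFI44L at 5.41, PON3 at -0.38 and RPS21 at -3.68.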

How the results depend on the processing

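Tests that leave out 1 or 2 libraries or the mitochondrially encoded genes, the covariate for coverage, the fit of the same 10 libraries with no pairing term, and the other settings of the principal components were chosen after seeing the data, and the others were planned. With a change of at least 2-fold asked for as well, the counts were 1433 (DPL against L), 938 (LDPL against L), 86 (LDPL against DPL), 146 (DLDPL against DPL), 695 (DLDPL against L) and 135 (LDPL against the midpoint), by construction. DESeq2 called 617 genes in LDPL against DPL, 33 in DLDPL against LDPL and 802 in DLDPL against DPL. Fitting the compared groups alone gave 178 genes in LDPL against DPL and 252 in DLDPL against DPL, with fewer libraries in the model. On RPKM, limma tested 10327 genes and called 209 in LDPL against DPL (pseudocount 1), 1864 in DLDPL against L (pseudocount 0.1), and 620 and 611 against the midpoint (pseudocounts 1 and 0.1). The cause of these differences, beyond fewer genes or libraries, was not tested. For DLDPL against LDPL, where edgeR called 0, array weights gave 1 gene and no filter on low counts gave 2, and the cause was not tested.

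The balance of directions differed between settings. With limma on RPKM and a pseudocount of 0.1 the median log2 change of all genes was -0.147 in DPL against L (1207 higher, 2662 lower), 0.105 in LDPL against DPL (212 and 57) and 0.138 in DLDPL against DPL (435 and 49). With array weights on log2(RPKM + 1), which leave the scaling as it was, the last 2 had 246 and 103, and 320 and 93. DPL against L then had 1816 and 2330 (median -0.038), where without weights it had 1195 and 2669 (median -0.116). After quantile normalisation of log2(RPKM + 1) the 3 comparisons had 1901 and 2214, 142 and 145, and 225 and 221 (medians -0.018, 0.008 and 0.001). The imbalance thus depended on the scaling, and in DPL against L also on the weight of single libraries.

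Without 1 library, DPL against L had 4774 to 4778 genes, LDPL against L 3635 (without L replicate 2), LDPL against DPL 264 (without DPL replicate 23), and DLDPL against DPL 345 to 409, lowest without DLDPL replicate 29. DLDPL against L had 2481 to 2802, DLDPL against LDPL 0 in each, and the midpoint 1031 to 1066. L and LDPL share 5 replicate numbers, but after removing group means no library correlated best with the one of its own number (r from -0.101 to 0.067), so they were not treated as pairs. A replicate block on these numbers gave 1813 genes, and the same 10 libraries with no pairing term 2176, with fewer libraries in both. In that fit without pairing, MYH3 in LDPL against L was reversed (log2 change 0.1, adjusted p = 0.91), and L replicates 1, 2 and 7, at 41.4, 226 and 60.6 CPM, are not among those libraries.

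Of 413 called pairs of a named gene and a comparison, 4699 alternative values were computed: 4228 kept the direction and the call, 470 kept the direction without passing the threshold and 1 was reversed. The list calls numbered 0 with an estimated correlation. The gap of L on the first principal component was 27.4% of the range with more genes, 12.5% on log2(RPKM + 1) and 28.9% without L replicate 2. Planned but not run were a sex covariate, since no Y-linked symbol was found, and rescaling RPKM by median ratios, in whose place size factors of DESeq2 were used in edgeR. Simulated 1.5-fold changes were recovered in 25.8% to 46.3% of genes over the 7 comparisons, so changes of that size can be missed. The simulations changed few genes, so these rates need not hold for the comparisons with L.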

Other observations

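The positions of LDPL between its parental breeds were computed after the results were seen, whereas the count of other splits of the libraries was planned.

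Further members of the fixed lists changed. In LDPL against L, KLF4 rose by 2.55 ± 0.26, CCN1 by 2.97 ± 0.29 and NR4A2 by 3.26 ± 0.43 on the log2 scale (SE, n = 8, adjusted p = 1.22e-08, 4.18e-09 and 1.08e-06). FST, an antagonist of myostatin, changed by -1.53 ± 0.31 (adjusted p = 0.000314), SIX4 by -0.85 ± 0.14 (adjusted p = 4.1e-05) and IGFBP5 by -1.68 ± 0.28 (adjusted p = 3.13e-05). KIT was higher than in DPL in LDPL (1.42 ± 0.33, adjusted p = 0.016) and in DLDPL (1.7 ± 0.33, adjusted p = 0.00277), but over the other settings these changes went down to 0.25 and 0.32, and the calls were lost in 3 of 10 and 2 of 13 (adjusted p up to 0.191 and 0.0776). ACSL1 and ACSS2, which activate fatty acids and acetate, were lower in LDPL than in DPL (-0.7 ± 0.16 and -0.55 ± 0.13, adjusted p = 0.0127 and 0.0153), and CNN1, a smooth muscle protein, was higher (0.88 ± 0.2, adjusted p = 0.0136). In DLDPL against DPL, IGFBP5 was higher (1.16 ± 0.28, adjusted p = 0.0141), and ETFDH and ESRRA were lower (-0.52 ± 0.11 and -0.72 ± 0.17, adjusted p = 0.00418 and 0.0108). Of these, ACSS2 in LDPL against DPL lost its call in 2 of 10 settings, ETFDH and ESRRA in 2 and 3 of 13, and FST in LDPL against L in 1 of 12 (adjusted p up to 0.072, 0.0742, 0.0802 and 0.069).

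With L at 0 and DPL at 1, LDPL lay at 0.74 for heat shock genes (95% bootstrap interval 0.61 to 0.87), 0.41 for nuclear genes of oxidative phosphorylation (0.11 to 0.71), 0.58 for fatty acid oxidation (0.37 to 0.81), 0.52 for the cell cycle (0.29 to 0.76) and 0.69 for matrix genes (0.19 to 1.89). The position for immediate early genes minus that for oxidative phosphorylation was 0.42 (0.1 to 0.73). To avoid choosing and measuring genes on the same libraries, genes called between L and DPL in one part of their libraries were placed with the other part. Over a mean of 2053 genes (2345 and 1761), LDPL lay at 0.77 (0.67 to 0.88). All these positions are on the log2 scale and include L, so a difference in handling between L and the other groups would enter them.

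Other splits of the same libraries into groups of the same sizes were fitted, 50 per comparison with the real one included. Where 1 of 50 splits, the real one, called as many genes, no other split drawn reached its count. So few splits, with no adjustment over comparisons, do not exclude chance, and they do not bear on separate handling of L. DPL against L had 4873 genes against 558 in the highest other split, LDPL against L 3793 against 1615, and LDPL against DPL 366 against 5. DLDPL against DPL had 526 against 149, DLDPL against L 2805 against 1068, and LDPL against the midpoint 1041 against 30. The splits for the midpoint mixed the L, DPL and LDPL libraries, so they cannot test departures from the midpoint where L and DPL differ. For DLDPL against LDPL the real count was 0, so all 50 splits called as many by construction, the highest 3, and the count of splits says nothing on chance there.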
